A study of Mus musculus with 24 samples.

How the data were processed

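Poly(A) RNA of 21 thymic lymphomas and 3 normal thymus samples was sequenced by the authors. Per the labels' protocols, RNA came from suspensions of lymphoma cells or thymocytes and was extracted with Maxwell RSC and RNeasy kits, with 1 batch date for all samples. Per the submitters' processing notes, the tools were cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, SAMtools and edgeR, and the genome build was GRCm38.p6; their settings and the strand of counting are not given in the sources used here. The authors deposited whole-number counts per gene symbol for all 24 libraries (21878 genes), which are not normalized. The authors also deposited a TPM table of the same libraries, with 21879 lines, of which 1 repeats a symbol, and column sums of 992063 to 995590. The authors' filtered count tables, of 12194 and 12109 genes, hold the thymus libraries with the 11 mutated or the 10 unmutated lymphomas. Their counts equal those of the table of all samples in 100% of cells, and their genes are those with a CPM above 1 in at least 2 libraries. A deposited CPM table of lymphomas chosen by Grb10 level was not used, because its column names do not say which are high or low, so no Grb10 comparison was run. Among the counted symbols, 3 had been turned into dates by a spreadsheet (0.0498% of counts), 1 antigen receptor segment was present, so T-cell receptor usage was not described, and no mitochondrially encoded gene was present.

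Lymphomas were assigned to the mutated or unmutated set from the column names of the authors' filtered tables alone, never from Ikzf1 counts. Which test called the mutations is not given in the sources used here. Library pairs were compared by a chi-square test of their counts. The statistic per degree of freedom was 51.6 to 358.3 between lymphomas and 10.1 to 35.8 between thymus libraries, so no pair agreed within sampling noise. Symbols were placed on GRCm38 with GENCODE M21: 20613 symbols (94.2%, with 97.7% of counts) were placed, 1238 were not found and 27 had more than 1 gene.

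Differences were tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts: TMM normalization, filterByExpr on low counts (13121 genes kept), glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. All lymphomas were compared with thymus in a model of 2 groups. The sets were compared with thymus and with each other in 1 model of 3 groups, which share an estimate of the spread. Group levels are means ± SD of CPM scaled by TMM. SE values are the fold change divided by the root of the F statistic. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. On simulated counts with 200 changed genes of 13121, the test found 47% of 2-fold and 76% of 4-fold changes for lymphomas against thymus, 37 and 79% for the mutated set against thymus, 50 and 75% for the unmutated set against thymus, and 67 and 86% between the sets. Unchanged genes made up 4.2, 2.2, 3.6 and 4.4% of the calls. Genes of a further list, raised for the test of lists, were counted among the calls. Each gene had 1 spread for all simulated libraries, while the real thymus libraries differed less than the lymphomas. The rates may therefore not hold for the real comparisons with thymus.

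The tests, gene lists and the rule for named genes were fixed before the data were examined. In each comparison the text names Ikzf1, Grb10, Ddc, Fignl1, Cobl, Trp53, Bcl11b, Notch1, Myc and Cdkn2a. Results for some further genes are not reported here. It also names the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 10 CPM in the higher group and, against thymus, a value outside the thymus range in at least 90% of the lymphomas. Gene models known only by a number, antigen receptor segments and symbols turned into dates are counted but not named. Of each list past the threshold it names up to 4 members with the smallest p, and of other lists up to 3. Col1a2, Pdgfrb and the per-lymphoma values were chosen after they were seen. The 34 lists with at least 3 measured members cover thymocyte stages, T-cell receptor signalling, Notch and p53 targets, cell cycle, replication histones, ribosome biogenesis, metabolism, interferon, NF-kB, PI3K and immediate-early genes, apoptosis, oncogenes, tumour suppressors, the Ikaros family, imprinted genes, neighbours of Ikzf1 and markers of other cell types. They were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01. In every comparison none of the lists passed with an estimated correlation, and for lists past the threshold that p is printed beside the preset one of the comparison. Some lists share members, such as Prss16 of the epithelial list with the named falls.

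Chromosome medians, window medians and every test on chromosome 15 were added after the data were seen. Ratios were taken for 8631 placed genes with a mean of at least 10 CPM. For each lymphoma, log2 of (CPM + 0.5) was set against the mean of the log2 values of thymus. Each thymus library was set against the mean of the other thymus libraries. Medians were taken per chromosome and per 5 Mb window with at least 20 of these genes. Limits of -0.5 for low and 0.3 for high were set after the values were seen. Medians were compared with 10000 random gene lists matched on expression, or on GC content of the longest coding transcript. Permutation tests used 1e+05 resamples, or all orders for 6 samples, and are two-sided. Computations other than the model fits used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Chance agreement from shared thymus libraries was simulated 20 times with unchanged groups.

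Alternatives fixed before the data were examined were DESeq2's size factors in edgeR, no low-count filter, a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, an added fold limit, limma on log2(TPM + 1) and log2(TPM + 0.1), the authors' filtered tables, a fit of lymphomas alone, fry and an estimated correlation for lists, 2 or 10 Mb around Ikzf1, and leaving out each thymus library. Leaving out each lymphoma, bounds without the highest lymphoma, covariates for library size or chromosome 15, leaving out chromosome 15, a rank-sum test, a depth limit of 24 M counts and other CPM minima for chromosome medians were added after the data were seen. Depth of 15 to 36.6 M counts limits the genes of a few counts per library, such as Cobl and Zcchc12.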

Results

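RNA was sequenced from 21 thymic lymphomas and 3 samples of normal thymus of female B6C3F1 mice, a hybrid strain. The labels describe 4 weekly doses of 1.6 Gy of carbon ions to the whole body, begun at 4 to 5 weeks of age. Carbon ions are heavy charged particles that lose much of their energy over a short track. The treatment label stands on the normal thymus samples as well, and their titles carry the mark 7W, which the labels do not explain. RNA came from suspensions of lymphoma cells or thymocytes, and libraries were made from poly(A) RNA. Following the column names of the authors' filtered tables, 11 lymphomas carried an Ikzf1 mutation and 10 did not. Lymphomas are named here by their library numbers. Total counts per library were 15 to 36.6 M in the lymphomas (23.5 ± 6.4 M, mean ± SD; M is 1e+06) and 24.5 to 27.5 M in normal thymus (26.4 ± 1.6 M). The mutated set had 24.7 ± 6.1 M and the unmutated set 22.1 ± 6.6 M. The 10 most abundant genes took 3.93 to 5.2% of counts in the lymphomas and 3.72 to 3.85% in thymus. The labels do not say whether each lymphoma came from its own animal, so p-values measure the spread between these samples.

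The lymphomas were first compared with normal thymus, to describe what separates the tumours from the tissue of origin. Myc, a proto-oncogene transcription factor, was higher in 21 of 21 lymphomas than in any thymus library, at 301 ± 98.3 CPM against 83.8 ± 9.79 (mean ± SD, n = 21 and 3; log2 fold change 1.84, SE 0.32, adjusted p = 0.000196). The tumour suppressor Trp53 was also higher in all 21, at 295 ± 30.5 CPM against 195 ± 2.47 (log2 fold change 0.60, SE 0.10, adjusted p = 0.000187). Bcl11b, a transcription factor needed for commitment to the T-cell lineage, was lower in all 21, at 355 ± 120 CPM against 996 ± 20.6 (log2 fold change -1.49, SE 0.24, adjusted p = 0.000104). Cdkn2a, which encodes the cell-cycle inhibitor p16 and the p53 activator p19Arf, rose from 0.208 ± 0.104 to 18.3 ± 25.7 CPM (adjusted p = 0.0104). Ddc, the aromatic amino acid decarboxylase gene that lies between Ikzf1 and Grb10, rose from 1.79 ± 0.464 to 49.2 ± 48.2 CPM and exceeded the thymus range in 19 lymphomas (adjusted p = 0.0234). In all, 4044 of 13121 tested genes (30.8%) differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2022 higher and 2022 lower. At least a 2-fold change was seen in 1907 of them, 993 higher and 914 lower.

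Other genes fixed before the data were examined did not pass the test. Ikzf1, which encodes the lymphoid transcription factor Ikaros, averaged 774 ± 465 CPM in the lymphomas and 970 ± 117 in thymus (log2 fold change -0.33, SE 0.50, adjusted p = 0.656), with 79.4 CPM in lymphoma 2 and up to 1870 CPM elsewhere. It passed with limma-voom (-0.78, adjusted p = 0.0224), the lowest of 8 settings that reached up to 0.705. Notch1, the receptor that drives T-cell specification, averaged 1110 ± 755 CPM against 253 ± 32.8 and lay above the thymus range in 17 lymphomas (log2 fold change 2.14, SE 0.90, adjusted p = 0.0725). It passed the threshold when lymphoma 7, 12 or 18 was left out (adjusted p = 0.0423, 0.0391 and 0.0389), and over 8 other settings its adjusted p ranged from 0.0001 to 0.255. It also passed with DESeq2 and limma-voom. Grb10, an imprinted gene for an adaptor of insulin and growth factor receptors, averaged 3.28 ± 5.62 CPM against 0.296 ± 0.0514 (adjusted p = 0.171). It passed with DESeq2 (log2 fold change 3.48, adjusted p = 0.0306), the lowest of 8 settings that reached up to 0.457. Fignl1 was at 93.9 ± 36.4 CPM against 92.7 ± 19.6 (adjusted p = 0.972). Cobl had too few counts to be tested, 39 over the lymphomas and 14 over thymus.

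**Figure D1:**
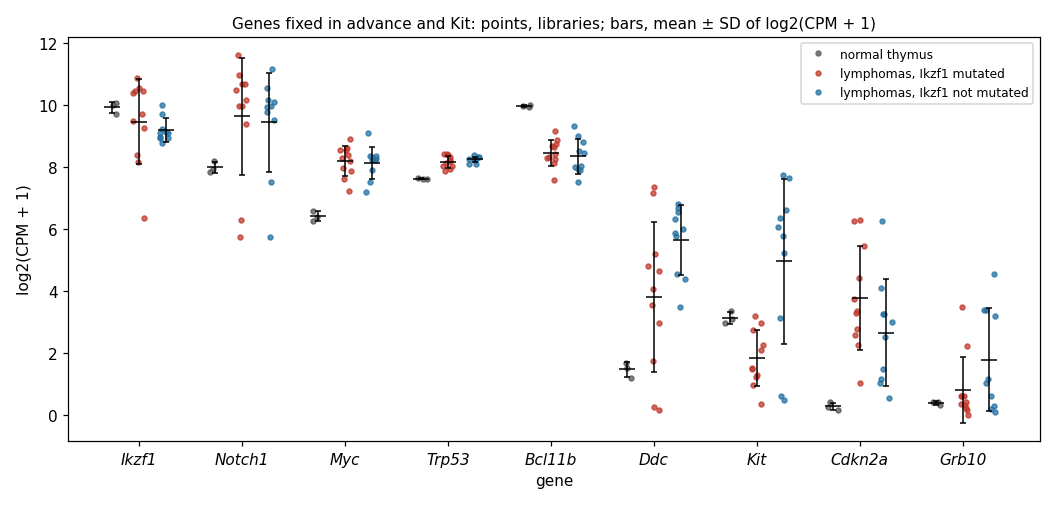
Levels of Kit and of genes fixed before the data were examined, as log2(CPM + 1) on the y axis, with 1 point per library for normal thymus (grey, n = 3), lymphomas with an Ikzf1 mutation (red, n = 11) and lymphomas without (blue, n = 10), and bars for the mean ± SD. All 21 lymphomas lie above the thymus libraries for Myc and Trp53 and below them for Bcl11b, while Notch1 spreads over a wide range.

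The largest rises were in genes that thymus hardly expressed. Vgll1, a co-factor of TEAD transcription factors, had no count in thymus and was at least 900-fold higher in the lymphomas (33.5 ± 42.8 CPM, adjusted p = 0.0124). Tmem132b and Nr3c2, the gene of the mineralocorticoid receptor, had 3 and 2 counts over the thymus libraries. Their ratios were 868 (counting interval 297 to 4210) and 484 (134 to 4000). Cym, the gene of the milk-clotting protease chymosin, was at 78.5 ± 78.6 CPM against 0.184 ± 0.0663 (log2 fold change 8.68, adjusted p = 0.000463), and Arg1, the urea-cycle enzyme arginase, at 39.7 ± 38.3 against 0.0995 ± 0.0559 (8.57, adjusted p = 2.14e-05). Trnp1 (log2 fold change 9.06), Ace (8.54), the gene of angiotensin-converting enzyme, Sall3 (8.36), Wisp1 (8.07) and Sh3rf3 (7.79) completed the 10 named by the rule. The largest falls were in Zcchc12 (log2 fold change -8.79), Prss16 (-7.58), a protease gene of cortical thymic epithelium, Adam12 (-7.41), Smoc1 (-6.96), Tdrp (-6.85), Gpc2 (-6.23), Slc6a19 (-6.23), Epb41l4b (-5.88), Pcbp3 (-5.42) and Tctex1d1 (-5.29). Smoc1 was at 82 ± 9.81 CPM in thymus and Tdrp at 67.6 ± 8.44, and each of the 10 was below the thymus range in 21 of 21 lymphomas.

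Marker lists of the later thymocyte stages and of the T-cell receptor were lower in the lymphomas, though not each member. Of 17 measured markers of thymocytes that carry both CD4 and CD8, 11 fell and none rose (13 adjusted over the list alone), among them Cd8b1, the CD8 beta chain, from 1430 ± 122 to 173 ± 167 CPM (log2 fold change -3.05), the recombinase gene Rag2 (-3.55), Cd1d1 (-1.67) and Aqp11 (-1.13). As a list they were lower than other genes (camera adjusted p = 0.000202, but adjusted p = 0.297 with an estimated correlation). Of 18 markers of mature thymocytes, 7 fell (7 adjusted over the list alone), with the activation marker Cd69 (-3), the homing receptor Ccr7 (-2.81), Gimap3 (-2.78) and Gimap6 (-2.14) as examples. Their adjusted camera p was 0.0108, against adjusted p = 0.796 with an estimated correlation. Of 22 genes of the T-cell receptor complex and its signalling, 11 fell (12 adjusted over the list alone), including Cd27 (-1.35), the receptor chains Cd247 (-1.18) and Cd3e (-1), and the adaptor Lat (-0.69). The adjusted camera p was 0.000876, and adjusted p = 0.573 with an estimated correlation.

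Lists of ribosome biogenesis, glycolysis, DNA replication and oxidative phosphorylation were higher as lists at the preset correlation, though few genes of replication and oxidative phosphorylation passed singly. Of 25 genes of ribosome biogenesis that Myc is known to induce, 22 rose and none fell (23 adjusted over the list alone), such as Polr1b (log2 fold change 1.52), a subunit of RNA polymerase I, Mybbp1a (1.45), Ddx21 (1.35) and Rrp12 (1.28). The list's adjusted camera p was 2.36e-11, and adjusted p = 0.304 with an estimated correlation. Of 25 genes of glycolysis and the hypoxia response, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with Egln3 (2.36), Pgam1 (1.75), Ldha (1.25) and Pgk1 (1.19) as examples (adjusted camera p = 1.72e-06; adjusted p = 0.297 with an estimated correlation). Of 27 genes of DNA replication, 5 rose (2 adjusted over the list alone), led by Mcm6 (0.78), Rrm1 (0.77), Pola1 (0.73) and Prim1 (0.52), and the list passed at an adjusted camera p of 0.00331 (adjusted p = 0.859 with an estimated correlation). Of 28 nuclear genes of oxidative phosphorylation, 6 rose (1 adjusted over the list alone), among them Atp5b (0.63), Atp5c1 (0.48), Sdhb (0.44) and Sdha (0.32), with an adjusted camera p of 0.00247 (adjusted p = 0.796 with an estimated correlation). Of 27 interferon-response genes, 6 fell (6 adjusted over the list alone), including Ifit1 (-2.85), Ifit3 (-2.34), Gbp4 (-1.78) and Stat2 (-0.80), with an adjusted camera p of 0.00577 (adjusted p = 0.796 with an estimated correlation).

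Markers of other cell types moved with the tumours too, in both directions. Of 14 macrophage and monocyte markers, 12 rose (12 adjusted over the list alone), for example Marco (log2 fold change 4.70), Cd14 (2.69), Apoe (1.87) and Cd68 (1.76, from 11.4 ± 1.56 to 38.9 ± 16.9 CPM). Of 11 fibroblast markers, 8 rose (8 adjusted over the list alone), for example Col1a1 (4.23, from 0.739 to 14 ± 10.5 CPM), Col3a1 (3.90), Sparc (3.30) and Fn1 (2.61). Adjusted camera p was 2.24e-06 for macrophages and 0.000105 for fibroblasts, with adjusted p = 0.297 with an estimated correlation in each. Of 11 neutrophil markers, 9 fell (9 adjusted over the list alone), with Camp (-4.29), S100a9 (-3.72), Ltf (-3.61) and S100a8 (-3.58) as examples. Of 11 thymic epithelial markers, 8 fell (8 adjusted over the list alone), with Prss16 (-7.58), Tbata (-6.09), Psmb11 (-5.94), the thymus-specific proteasome subunit, and Krt18 (-3.05) as examples. Adjusted camera p was 4.71e-05 for neutrophils (adjusted p = 0.297 with an estimated correlation) and 2.24e-06 for epithelium (adjusted p = 0.156 with an estimated correlation). Of 12 genes of natural killer and cytotoxic cells, 2 rose and 6 fell (2 and 7 adjusted over the list alone), with Klrd1 (-3.45), Klrk1 (-3.19) and Nkg7 (-3.08) lower and the Fc receptor gene Fcgr3 (2.18), which macrophages also express, higher (adjusted camera p = 0.0479; adjusted p = 0.796 with an estimated correlation).

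The comparison with thymus rested on 3 control libraries, and leaving out thymus 1, 2 or 3 left 2278, 1929 or 2545 genes past the threshold. Limma-voom called 8777. Without each of them in turn the calls of Ddc (adjusted p = 0.0989, 0.0911 and 0.0831), Vgll1 (0.0547, 0.06 and 0.0506), Ace (0.078, 0.0865 and 0.0678), Sall3 (0.0671, 0.0892 and 0.0811) and Wisp1 (0.0971, 0.112 and 0.0896) were lost. Sh3rf3 lost its call without thymus 1 (0.0668) or 3 (0.0603), and Cdkn2a without thymus 2 (0.0653) or 3 (0.051). Trp53, Bcl11b, Myc, the other 5 named rises and the 10 named falls kept theirs in all 24 fits that left out 1 library. Ddc also lost its call on log2(TPM + 0.1) (0.0726) and in libraries of at least 24 M counts (0.0871), over a range from 7.46e-05. Wisp1 lost it in the latter (0.0573). On log2(TPM + 1), Ace, Sall3, Sh3rf3 and Wisp1 did not pass, with adjusted p from 0.0729 for Ace to 0.152 for Sh3rf3. On that scale 4024 genes passed, of which 35.6% were higher, against 50% here.

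The series title names a partial deletion of chromosome 11, and Ikzf1 lies near the start of that chromosome (11685003 to 11772926 in GRCm38), followed by Fignl1 (11787431 to 11808962), Ddc (11814101 to 11898144) and Grb10 (11930508 to 12038683). Over the first 10 Mb of chromosome 11, with 52 measured genes, 6 lymphomas had a median log2 ratio to thymus between -1.01 and -0.77. These were lymphomas 4 (-0.88), 10 (-0.94), 13 (-0.88) and 17 (-0.77) of the mutated set and 30 (-1.01) and 31 (-0.83) of the unmutated set. By 5 Mb window, lymphoma 17 was at or below -0.5 only from 5 to 10 Mb (-0.86), while lymphomas 4, 10, 13, 30 and 31 were so in both windows. The other 15 lymphomas lay between -0.15 and 0.1 and the thymus libraries, each set against the other thymus libraries, between -0.03 and 0.07. In the 6, between 59.6 and 84.6% of the genes were below -0.5, against at most 26.9% in any other lymphoma, and beyond 30 Mb their medians were -0.02 to 0.15. None of 10000 random gene lists matched on expression was as low in any of the 6. The share of low lymphomas was 4 of 11 in the mutated and 2 of 10 in the unmutated set (Fisher's exact test, two-sided p = 0.635). From 20 to 25 Mb (22 genes), lymphomas 18 (-1.12), 31 (-0.73) and 4 (-0.50) were low, and from 65 to 70 Mb (38 genes), lymphoma 32 (-0.55). Ikzf1 itself lies in a window with 3 measured genes, too few for a median here. Its own level in lymphomas 4, 10, 13, 17, 30 and 31 was 603, 707, 280, 330, 589 and 430 CPM, against 835 to 1050 in thymus. Lymphomas 2, 18, 19, 20, 21, 22 and 34, without the low stretch, were below thymus as well, at 79.4 to 560 CPM. The level of Ikzf1 thus does not show whether the low stretch reached it.

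**Figure D2:**
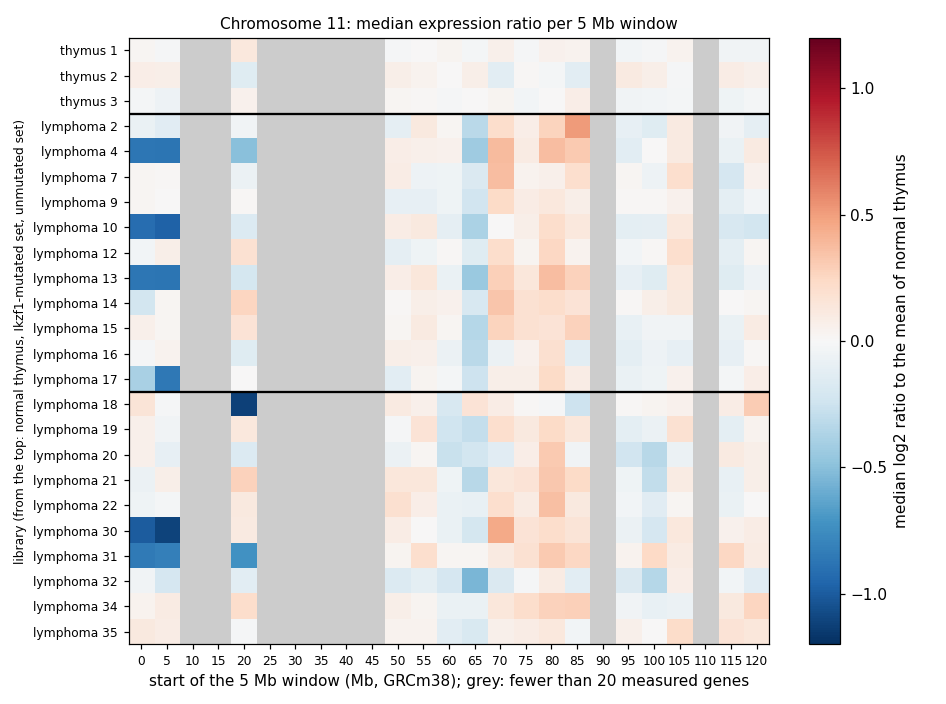
Heat map of chromosome 11 in 5 Mb windows from left to right (position in Mb) for each of 24 libraries from top to bottom, coloured by the median log2 ratio of measured genes to the mean of normal thymus; windows with fewer than 20 measured genes are grey. Lymphomas 4, 10, 13, 30 and 31 are at or below -0.5 in both windows of the first 10 Mb, and lymphoma 17 only in that from 5 to 10 Mb. The thymus libraries, each set against the mean of the other thymus libraries, stay between -0.15 and 0.13 in every drawn window.

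Within 5 Mb on each side of Ikzf1 only 9 of 20 protein-coding genes were measured, and their median log2 fold change against thymus was 0.80 over all lymphomas, with 1 gene (Ddc) past the threshold (camera p = 0.463; p = 0.681 with an estimated correlation). The median was 0.72 in the mutated set (p = 0.733), 0.88 in the unmutated set (p = 0.265) and -0.42 for mutated against unmutated (p = 0.0553; p = 0.28 with an estimated correlation). With 10 Mb on each side (94 measured genes) the 3 medians against thymus were -0.03, -0.12 and -0.08, the opposite sign. Lymphomas were split at 2 CPM of Grb10, in the gap between 1.24 and 3.69 CPM, and no test of clustering was made. No pooled correlation with Ikzf1 was computed, so a relation over all lymphomas was not tested. Each group covers a narrower range of Grb10, which can weaken r. In the 15 lymphomas with under 2 CPM of Grb10 (0 to 1.24), Pearson's r of log2(CPM + 1) was 0.34 (permutation p = 0.192) and Spearman's rho 0.36 (permutation p = 0.184), and r was 0.06 without the 2 lymphomas farthest from the median of Ikzf1. In the 6 with 3.69 to 22.19 CPM (7 and 12 of the mutated set, 21, 30, 34 and 35 of the unmutated set), r was -0.31 (exact permutation p = 0.556) and rho -0.09 (exact permutation p = 0.919), and r was 0.92 over the 4 left without the 2 farthest, so no relation was established. Thymus had 0.24 to 0.33 CPM.

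The design text sets lymphomas with and without an Ikzf1 mutation each against normal thymus, to find genes tied to mutation status. Both sets shared the main changes: Myc was at 306 ± 96.1 CPM in the mutated set (n = 11; log2 fold change 1.87) and 295 ± 106 in the unmutated set (n = 10; 1.82), Trp53 at 288 ± 38.4 (0.57) and 301 ± 18.2 (0.63), and Bcl11b at 362 ± 103 (-1.46) and 346 ± 143 (-1.52). All 6 values passed, with the highest adjusted p at 0.000636. Ikzf1 was at 934 ± 586 CPM in the mutated set (log2 fold change -0.05, adjusted p = 0.951) and 597 ± 182 in the unmutated set (-0.70, adjusted p = 0.291). Thymus had 835 to 1050 CPM. The mutated mean covers lymphomas 7, 12, 14, 15 and 16 at 1320 to 1870 CPM, lymphoma 9 at 835, and 2, 4, 10, 13 and 17 at 79.4 to 707. Unmutated lymphomas 32 and 35 were at 1010 and 835 CPM and the others at 430 to 589. Ikzf1 passed in the mutated set with limma-voom (-0.86, adjusted p = 0.0436, over a range that reached 1) and in the unmutated set on the authors' filtered table (-0.71, adjusted p = 0.0232, over a range that reached 0.342). Ddc rose in both, to 38.7 ± 57.3 CPM (4.43, adjusted p = 0.0392) and 60.7 ± 35.1 CPM (5.08, adjusted p = 0.0183), above the thymus range in 9 of 11 and 10 of 10. Cdkn2a rose as well (6.79, adjusted p = 0.0103, and 5.86, adjusted p = 0.0139). Notch1 had log2 fold changes of 2.30 (adjusted p = 0.074) and 1.95 (adjusted p = 0.104). It passed in both sets with DESeq2 (adjusted p = 0.0163 and 0.0405) and limma-voom, over ranges of 0.000483 to 0.0835 and 0.00347 to 0.119. Grb10 was at 1.49 ± 3.02 CPM (2.31, adjusted p = 0.332) and 5.24 ± 7.19 (4.12, adjusted p = 0.0974). It passed in the unmutated set with DESeq2 (4.16, adjusted p = 0.00914) and limma-voom (2.15, adjusted p = 0.0347), over a range that reached 0.113. Fignl1 was at 80.9 ± 26.4 CPM (-0.20, adjusted p = 0.676) and 108 ± 41.6 (0.22, adjusted p = 0.62). Cobl, not tested, had 27 and 12 counts against 14 in thymus. Against thymus, 3412 genes passed in the mutated set (1713 higher, 1699 lower) and 4642 in the unmutated set (2366 higher, 2276 lower).

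Among the largest changes of the mutated set, Ace was at 96.5 ± 74.1 CPM (log2 fold change 9.18, adjusted p = 0.0119). Elavl4, the gene of a neuronal RNA-binding protein, was at least 283-fold and Vgll1 at least 739-fold higher. These bounds were 173-fold without lymphoma 16 and 447-fold without lymphoma 15. Lmcd1 had a ratio of 2370 (counting interval 425 to 93600, on 1 count in thymus), and the glutamate receptor gene Grik1 rose by 7.84 on log2. In the unmutated set, Cym was at 117 ± 93.6 CPM (9.26, adjusted p = 0.000134). There Vgll1 was at least 1080-fold and Igfbpl1 at least 963-fold higher. Igfbpl1 was carried by lymphomas 19 (227 CPM) and 30 (105), with a median of 1.03 CPM, and its bound was 393-fold without lymphoma 19. The ratios of Kank4 and the homeobox gene Emx2 were 1100 (305 to 9080) and 935 (259 to 7720). In the mutated set Emx2 was at 0 CPM in lymphomas 4 and 7 and at 13.4 to 47.8 CPM in the others. Zcchc12 and Lypd1 had no count in the unmutated set and were at least 1330-fold and at least 1120-fold lower than in thymus. Lypd1 was at 21.7 CPM in lymphoma 2 of the mutated set and at most 0.417 CPM in the others of that set. In the mutated set Zfp827 (-5.83) and S100a10 (-5.23) were among the largest falls. In the unmutated set Zfp827 was at 16.4, 11.1 and 3.35 CPM in lymphomas 19, 35 and 20, and at most 0.478 CPM in the others. A gene named for 1 set only by the rule need not differ between the sets. The other named genes of these comparisons were those already described for all lymphomas. Without any 1 thymus library the mutated-set calls of Ddc (adjusted p = 0.116 to 0.135), Vgll1 (0.0686 to 0.0836), Elavl4 (0.0743 to 0.0903), Lmcd1 (0.126 to 0.156), Ace (0.0508 to 0.0689), Sh3rf3 (0.062 to 0.0796) and Grik1 (0.0525 to 0.095) were lost. So were the unmutated-set calls of Ddc (0.0654 to 0.0779), Igfbpl1 (0.107 to 0.117), Kank4 (0.0708 to 0.0857) and Sall3 (0.0624 to 0.0782). Cdkn2a lost its call without thymus 2 in the mutated set (0.0659) and without thymus 2 (0.068) or 3 (0.0573) in the unmutated set. In the mutated set Ddc also lost its call with limma-voom (0.0694) and on the authors' filtered table (0.0879), over a range from 0.000713. Lmcd1 lost it without a low-count filter (0.0515, over a range from 4.59e-05). Igfbpl1 lost its call on the authors' table of the unmutated set (0.061, over a range from 1.1e-05).

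Several gene lists had different counts against thymus in the 2 sets, and all but NF-kB of those in this paragraph also differed between the sets at the preset correlation. Ribosome biogenesis genes rose in 20 of 25 in the mutated and 23 of 25 in the unmutated set (22 and 24 adjusted over the list alone; adjusted camera p = 6.01e-10 and 5.04e-13; adjusted p = 0.35 and 0.294 with an estimated correlation). Oxidative phosphorylation genes rose in 1 of 28 (adjusted camera p = 0.0831) and in 16 of 28 (20 adjusted over the list alone; 1.24e-05; adjusted p = 0.446 with an estimated correlation). DNA replication genes rose in 2 of 27 and 14 of 27 (0 and 16 adjusted over the list alone; adjusted camera p = 0.0459 and 0.000253; adjusted p = 0.994 and 0.687 with an estimated correlation). T-cell receptor genes fell in 7 and 14 of 22 (7 and 16 adjusted over the list alone; adjusted camera p = 0.0112 and 2.14e-05; adjusted p = 0.74 and 0.294 with an estimated correlation). NF-kB target genes passed only in the unmutated set, where 3 rose and 8 fell of 20 (3 and 9 adjusted over the list alone; adjusted camera p = 0.0444; adjusted p = 0.687 with an estimated correlation). That list was not past the threshold in the test of the difference between the sets (adjusted camera p = 0.184). Cholesterol synthesis genes, which did not pass as a list, rose in 0 and 7 of 21.

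For the other lists that passed against thymus in at least 1 set, the test pointed the same way in both. Among them, markers of mature thymocytes and neutrophils also differed between the sets at the preset correlation. Glycolysis genes rose in 13 and 14 of 25 (16 and 14 adjusted over the list alone; adjusted camera p = 1.5e-07 and 2.61e-05; adjusted p = 0.227 and 0.294 with an estimated correlation). Macrophage markers rose in 11 and 12 of 14 (13 and 12 adjusted over the list alone; adjusted camera p = 7.23e-06 and 1.18e-05; adjusted p = 0.35 and 0.301 with an estimated correlation). Fibroblast markers rose in 8 and 8 of 11 (8 and 8 adjusted over the list alone; 6.7e-05 and 4e-04; adjusted p = 0.35 and 0.301 with an estimated correlation). Markers of thymocytes with both CD4 and CD8 fell in 8 and 8 of 17 (8 and 11 adjusted over the list alone; adjusted camera p = 0.000263 and 0.000253; adjusted p = 0.35 and 0.301 with an estimated correlation). Those of mature thymocytes fell in 5 and 8 of 18 (5 and 8 adjusted over the list alone; 0.0459 and 0.0031; adjusted p = 0.994 and 0.568 with an estimated correlation). Interferon genes fell in 4 and 6 of 27, with 2 rises in the unmutated set (4 and 5 falls adjusted over the list alone; adjusted camera p = 0.00778 and 0.0165; adjusted p = 0.994 and 0.69 with an estimated correlation). Neutrophil markers fell in 8 and 9 of 11 (9 and 9 adjusted over the list alone; adjusted camera p = 6.7e-05 and 3.19e-05; adjusted p = 0.35 and 0.294 with an estimated correlation). Epithelial markers fell in 7 and 7 of 11 (7 and 8 adjusted over the list alone; 1.14e-06 and 2.14e-05; adjusted p = 0.148 and 0.294 with an estimated correlation). Natural killer genes passed only in the mutated set (2 rises and 4 falls of 12, 2 and 6 adjusted over the list alone; adjusted camera p = 0.0494; adjusted p = 0.994 with an estimated correlation). The counts were larger in the unmutated set (2 rises and 7 falls, 2 and 8 adjusted over the list alone; 0.0772), and the difference between the sets did not pass (0.933).

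Of the genes called against thymus, 1483 rose in both sets and 1385 fell in both, where independent lists of these sizes would share 308.9 and 294.7. The fold changes of the sets correlated across genes, which are not independent replicates, with r = 0.88. In 20 simulations of unchanged groups against the same 3 simulated thymus libraries r averaged 0.82, because the controls are shared. Each gene had 1 spread for all simulated libraries. The real thymus libraries differed less than the lymphomas did, with a chi-square per degree of freedom of 10.1 to 35.8 against 51.6 to 358.3. The simulated agreement may therefore be too high. The covariance was 1.92 against 0.37 in the simulations, a difference of 1.55, and 85.7% of genes had the same sign against 78.3%. The simulations called 0 genes in both, against 2868. The controls could not be split, with 3 libraries, so part of the excess may come from them. Of 544 genes called in the mutated set alone, 60 also differed between the sets, and of 1774 called in the unmutated set alone, 303 did. Without thymus 1, 2 or 3 the mutated-set count was 1895, 1441 or 2128, and without thymus 1 or 2 the unmutated-set count was 2958 or 2856, while limma-voom called 7866 and 8308.

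The sets were then compared directly. Kit, the stem cell factor receptor of early progenitors, was lower in lymphomas with an Ikzf1 mutation, at 3.21 ± 2.62 CPM against 74.6 ± 75.5 (n = 11 and 10; log2 fold change -4.55, SE 0.80, adjusted p = 0.0101). In the unmutated set it was at 0.393, 0.524 and 7.67 CPM in lymphomas 21, 31 and 19, while the highest mutated value was 8.19. In the other unmutated lymphomas it ranged from 36.2 CPM in lymphoma 22 to 211 in lymphoma 30. Thymus had 6.71 to 9.13 CPM of Kit. Within the Ikaros family of zinc finger genes, Ikzf2 (Helios) was higher in the mutated set, at 319 ± 151 CPM against 126 ± 74.6 (1.34, adjusted p = 0.0255), and Ikzf3 (Aiolos) at 351 ± 91.8 against 196 ± 85 (0.84, adjusted p = 0.0332). Ikzf1 itself was at 934 ± 586 against 597 ± 182 CPM and did not pass (0.65, SE 0.35, adjusted p = 0.276). In total 706 of 13121 genes differed, 319 higher and 387 lower in the mutated set, 207 of them by at least 2-fold (122 higher, 85 lower).

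The other fixed genes did not differ past the threshold: Grb10 (1.49 ± 3.02 against 5.24 ± 7.19 CPM, adjusted p = 0.267), Ddc (adjusted p = 0.643), Fignl1 (0.238), Trp53 (0.612), Bcl11b (0.877), Notch1 (0.74), Myc (0.904) and Cdkn2a (0.508). Cobl, not tested, had 27 and 12 counts. Eng, the endothelial TGF-beta co-receptor endoglin, was higher in the mutated set, at 12.3 ± 14.4 against 1.24 ± 0.542 CPM (log2 fold change 3.31, adjusted p = 0.0134), as were Susd4 (6.06), Nsg1 (5.56), the protease gene Klk8 (5.27), P3h4 (2.85) and Adam19 (2.80), each above the unmutated range in 5 or 6 of 11 lymphomas. Adam19 was below that range in 2 lymphomas and Eng in 1. Thymus had 13.3 to 15.1 CPM of Eng, 18.3 to 24.1 of Klk8, 12.2 to 16.9 of P3h4 and 4.7 to 5.41 of Nsg1. Every unmutated lymphoma lay below thymus for these genes, so their difference between the sets does not show a rise over thymus. For Susd4 (thymus 0.395 to 0.753 CPM) and Adam19 (11.1 to 13.9), unmutated lymphomas lay on both sides of thymus. The proteoglycan gene Sdc2 (4.93) was above the unmutated range in 3 of 11 and below it in 3, with medians of 0.374 and 0.328 CPM. Dock1 (3.60) was above it in 3 of 11, with medians of 0.626 and 0.515 CPM. The growth factor gene Igf2 had the largest rise (10.08, adjusted p = 0.0134), but on 4 of 11 lymphomas above the unmutated range. Lymphomas 12 (469 CPM) and 7 (75.5) carried it, while lymphomas 9 and 13 were at 0.744 and 0.275 CPM. Sema6d (3.41) rested on lymphoma 7, with 145 CPM, and fell to 0.19 without it (adjusted p = 0.789). Besides Kit, the genes lower in the mutated set by this rule were Ripk4 (-3.76), Bex1 (-3.36), Ly6d (-2.87, 36.1 ± 56.7 against 264 ± 260 CPM), Sh2d5 (-2.50), the vitamin D receptor gene Vdr (-2.42), S100a10 (-2.35) and the cornified envelope gene Evpl (-2.16). The prolactin receptor gene Prlr (-4.82) rested on lymphoma 18, at 207 CPM, and was 0.96 without it (adjusted p = 0.468), and Fgfr1 (-3.59) on lymphoma 20, at 131 CPM (-0.99 without it, adjusted p = 0.109).

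Of the 20 genes named for this comparison, Susd4, Nsg1, Klk8, Sdc2, Eng, Kit, Sh2d5 and Evpl kept their call in all 21 fits that left out 1 lymphoma, with a highest adjusted p of 0.0482, for Sdc2 without lymphoma 34. Log2 fold changes still moved over these fits, for example 5.09 to 7.61 for Nsg1, 5.35 to 7.44 for Susd4 and 4.04 to 5.13 for Sdc2. Igf2 kept its call in 18 and fell under the low-count filter without lymphoma 7, 9 or 12. The call was lost in 17 of these fits for Vdr (highest adjusted p = 0.102, without lymphoma 19), in 16 for Prlr, and in 15 for Adam19 (0.0956, without lymphoma 2). It was lost in 13 each for Ly6d (0.0753, without lymphoma 34) and S100a10 (0.0741, without lymphoma 35), and in 11 for Dock1 (0.101, without lymphoma 10). In 10 each it was lost for P3h4 (0.0676, without lymphoma 12) and Bex1 (0.0762, without lymphoma 18), in 9 for Sema6d, and without lymphoma 20 (0.0568) or 34 (0.0583) for Ripk4. A rank-sum test, exact per gene, called none of the 20 and limma-voom called 2, Sh2d5 and Evpl. DESeq2 kept 17, a library-size covariate 16, no low-count filter 12 and a fit of lymphomas alone 6 of 14.

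With each library's chromosome 15 median in the model, Igf2 alone of the 20 kept its call, but the lost calls were of several kinds. Log2 fold changes were no smaller for Sdc2 (5.23), P3h4 (3.69), Vdr (-3.42) and Evpl (-2.61), and near those above for Nsg1 (5.14) and Ripk4 (-3.74). They shrank for Kit (-1.27), Sh2d5 (-0.70), S100a10 (-0.84) and Adam19 (0.22), and Prlr turned to 2.29. The number of differing genes was 1269 with DESeq2, 388 in a fit of lymphomas alone and 225 with the rank-sum test. The adjusted p of Kit ranged from 2.44e-07 to 0.652 over 10 settings.

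Lists of oxidative phosphorylation, mitosis, histones, ribosome biogenesis, DNA replication and cholesterol synthesis were lower in the mutated set. Of 28 oxidative phosphorylation genes, 8 fell (16 adjusted over the list alone), such as Cox6c (log2 fold change -0.86), Cyc1 (-0.62), Ndufa4 (-0.45) and Cox5a (-0.41), with an adjusted camera p of 9e-11 and adjusted p = 0.349 with an estimated correlation. Of 25 mitosis genes, 6 fell (11 adjusted over the list alone), such as Bub1b (-0.60), the kinase gene Aurka (-0.53), Cdc25c (-0.52) and Cdk1 (-0.40) (adjusted camera p = 1.1e-08; adjusted p = 0.516 with an estimated correlation). Replication-dependent histone genes fell in 3 of 15 (7 adjusted over the list alone), with Hist1h3c (-1.72), Hist1h2bk (-1.66) and Hist1h4d (-1.23) (adjusted camera p = 0.00046; adjusted p = 0.574 with an estimated correlation). These histone transcripts largely lack poly(A) tails, and the libraries were made from poly(A) RNA. Ribosome biogenesis genes fell in 1 of 25, Bop1 (-0.60) (9 adjusted over the list alone; adjusted camera p = 6.87e-07; adjusted p = 0.536 with an estimated correlation). None of 27 DNA replication genes passed singly (0 adjusted over the list alone), but the list was lower (median -0.26; adjusted camera p = 5.11e-05; adjusted p = 0.654 with an estimated correlation). Cholesterol synthesis genes fell in 1 of 21, Sqle (-0.60) (1 adjusted over the list alone; adjusted camera p = 0.0365; adjusted p = 0.8 with an estimated correlation). Bop1, Sqle, Cox6c and Cyc1 lie on chromosome 15, where expression was higher in most unmutated lymphomas. Without the genes of that chromosome no member of the ribosome and cholesterol lists passed and 6 of oxidative phosphorylation fell.

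Other lists were higher in the mutated set. T-cell receptor genes rose in 4 of 22 (12 adjusted over the list alone), namely the co-stimulatory receptor Cd28 (1.97), Lcp2 (0.76), Cd27 (0.61) and the kinase gene Zap70 (0.38) (adjusted camera p = 1.77e-06; adjusted p = 0.315 with an estimated correlation). The Ikaros family rose in 2 of 5 (4 adjusted over the list alone; adjusted camera p = 0.00279; adjusted p = 0.0848 with an estimated correlation). Known T-lymphoma oncogenes rose in 3 of 19 (3 rose and 1 fell adjusted over the list alone), with Rasgrp1 (1.86), Stat5b (0.54) and Nras (0.20) (adjusted camera p = 0.0276; adjusted p = 0.315 with an estimated correlation). Immediate-early genes rose in 2 of 15 (3 adjusted over the list alone), with Egr3 (2.70) and Egr1 (2.09) (adjusted camera p = 0.0186; adjusted p = 0.516 with an estimated correlation). PI3K pathway genes rose in 3 of 29 (3 adjusted over the list alone), among them Igf2 and Pik3ca (0.33) (adjusted camera p = 0.0428; adjusted p = 0.516 with an estimated correlation). Markers of mature thymocytes passed as a list with 0 of 18 past the threshold singly (8 adjusted over the list alone; median 0.70; adjusted camera p = 0.0126; adjusted p = 0.654 with an estimated correlation). Erythroid markers rose in 2 of 8 (6 adjusted over the list alone), with the beta-globin genes Hbb-bt (2.10) and Hbb-bs (1.9) (adjusted camera p = 0.00665; adjusted p = 0.547 with an estimated correlation). Neutrophil markers passed as a list with 0 of 11 past the threshold and a median of 1.43 (0 adjusted over the list alone; adjusted camera p = 0.0429; adjusted p = 0.654 with an estimated correlation). With the chromosome 15 median in the model the oncogene (adjusted camera p = 0.0782), PI3K (0.107) and cholesterol (0.455) lists lost their call and NF-kB targets gained it (0.0457; adjusted p = 0.772 with an estimated correlation). The others kept it at the preset correlation, such as oxidative phosphorylation (4.93e-15; adjusted p = 0.354 with an estimated correlation) and mitosis (6.87e-10; adjusted p = 0.536 with an estimated correlation). With the genes of chromosome 15 left out, cholesterol (0.101), PI3K (0.077) and neutrophil (0.0683) lists lost their call.

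Expression over chromosome 15 also differed. The median log2 ratio to thymus over 355 genes of chromosome 15 was at least 0.3 in 7 of 10 unmutated lymphomas (18, 20, 22, 30, 32, 34 and 35) and in 1 of 11 mutated ones (12), at 0.46 to 0.67 in these 8. Those 7 unmutated lymphomas were the ones with 36.2 to 211 CPM of Kit. They also had 7.5 to 30.9 CPM of Sh2d5, against 0.72 to 3.02 in unmutated lymphomas 19, 21 and 31. Lymphoma 12, however, had 1.32 CPM of Kit and 3.99 of Sh2d5. The set means were 0.39 ± 0.24 and 0.06 ± 0.19 (permutation p = 0.00412, adjusted p = 0.0824 over 20 chromosomes; Fisher's exact p = 0.00752, adjusted p = 0.15), so the difference did not pass after adjustment. Chromosome 15 held 3.9% of placed tested genes but 24.8% of those lower in the mutated set (93 of 375), among them Prlr, Ly6d and Vdr. With the chromosome 15 median of each library in the model, 9 genes differed between the sets, against 706 without it. For called genes on other chromosomes the median absolute log2 fold change went from 0.547 to 0.5 and the median SE of all called genes from 0.132 to 0.164, so the fall in calls does not show that these differences went away. The absolute value disregards direction, so it does not show that they stayed either. Leaving out lymphoma 31 raised the count to 1221, and leaving out 34, 18, 22, 35, 30 or 17 lowered it to 301, 409, 414, 417, 420 or 447.

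**Figure D3:**
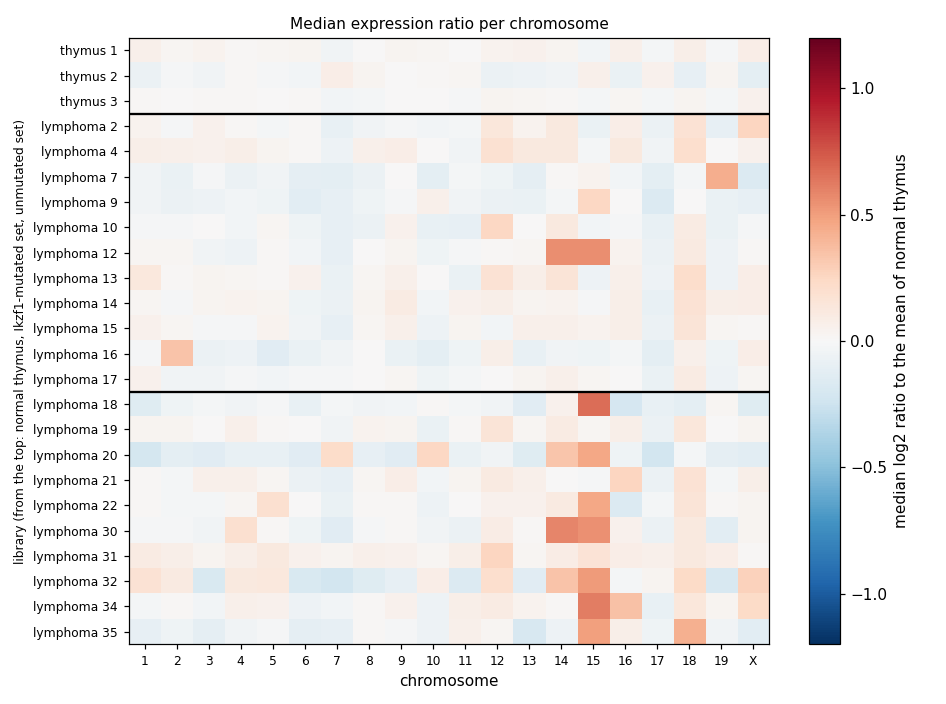
Heat map of the median log2 ratio to the mean of normal thymus for each of 24 libraries (top to bottom) and 20 chromosomes (left to right). Chromosome 15 is at 0.46 to 0.67 in lymphomas 12, 18, 20, 22, 30, 32, 34 and 35. The 3 thymus libraries, each set against the mean of the other thymus libraries, lie between -0.03 and 0.06 on that chromosome.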

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

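Of the tests in this part, those on macrophage co-variation and on other splits of the samples were chosen before their results were seen; those on fibroblast genes, from which Col1a2 and Pdgfrb were set apart after their values were seen, on chromosome 11, on the share of T cells, on library size and on chromosome 15 were chosen only after the result was seen.

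In the unmutated set (n = 10), 9 of 72 tested values had a library far from the rest, where chance gives about 1 in 20. Genes named because 1 library raised the mean of the set, such as Prlr and Fgfr1, and genes near the floor, such as Igf2 and Adam12, add to this count by selection, so it shows no excess of its own. Prlr was at 207 CPM in lymphoma 18, with the next lymphoma at 1.6, and Fgfr1 at 131 CPM in lymphoma 20, with the next at 5.6. Lymphoma 21 stood apart for Susd4 (3.74 CPM, next 1.24), Nsg1 (1.84, next 0.127) and Dock1 (4.85, next 1.24), all genes higher in the mutated set. Lymphoma 31 stood apart for Adam12 (1.21 CPM, next 0.262), lymphoma 35 for Tdrp (2.43, next 0.701) and lymphoma 20 for Igf2 (0.234, next 0.0564). The chromosome 10 median of lymphoma 20 was 0.25, with the next at 0.08. The 706 genes that differed between the Ikzf1 sets are genes whose difference from thymus differed between them.

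The real grouping gave 4044 genes for lymphomas against thymus, 3412 for the mutated and 4642 for the unmutated set against thymus and 706 between the sets. In 100 splits of the same samples into groups of the same sizes, the real one included, only 1 split, the real one, reached each count. The highest of the others called 85, 38, 132 and 21 genes, so chance assignment of samples is an unlikely origin of each count. It is not excluded, since 100 splits can give no share under 1 in 100. Against thymus, every other split also placed thymus libraries among the lymphomas, which can widen the spread of that group and lower its count.

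The low expression of the first 10 Mb of chromosome 11 in lymphomas 4, 10, 13, 17, 30 and 31 was set against library size, GC content and loss of a copy. Library size or normalization would lower the rest of the chromosome too, yet the lowest median beyond 30 Mb in these lymphomas was -0.02. With GC-matched lists, 0 of 10000 were as low in any of them, which argues against GC content. Loss of 1 of 2 copies stays open: at least 59.6% of the genes lay below -0.5 in each, and the medians of -1.01 to -0.77 lie near the log2 ratio of -1 that 1 copy in place of 2 would give, so a candidate explanation is a deletion carried by most cells of these tumours. In lymphoma 17 the low stretch was partial: within the first 10 Mb only the window from 5 to 10 Mb was at or below -0.5 (-0.86). No DNA was analysed here.

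Markers of macrophages and fibroblasts were higher in the lymphomas, while neutrophil and thymic epithelial markers were lower. A lower share of T cells would raise the markers of every other cell type only if the mix of those other cells stayed the same. The neutrophil median was -3.22 and the epithelial median -2.38, which argues against a lower share with an unchanged mix. A lower share with a changed mix was not tested. Macrophages in the suspensions stay open: the 12 risen macrophage genes varied together between lymphomas (mean Spearman rho 0.52, against 0.06 for the 95th percentile of 10000 random lists), and Cd68 was at 38.9 CPM, with Fcgr3 of the cytotoxic list rising alongside. Fibroblasts may likewise account for 6 of the 8 risen fibroblast genes (mean rho 0.57, random 95th percentile 0.16), of which Col1a1 was at 14 CPM. Col1a2 (187 ± 247 CPM against 1.93 in thymus) and Pdgfrb (183 ± 200 against 6.29) varied apart from those 6. Their mean rho with the 6 was -0.11 (bootstrap interval -0.49 to 0.28) and -0.19 (-0.5 to 0.17), against at least 0.46 for each of the 6. That argues against fibroblasts alone as their source. Because these 2 genes were set apart after their values were seen, the choice itself favours the contrast, and fibroblasts are not excluded. Expression by lymphoma cells was not tested.

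The difference between the Ikzf1 sets was set against library size and chromosome 15 dose. With log2 library size in the model 623 of the 706 genes were called again, which argues against library size as the whole cause. For genes on chromosome 15 a higher dose in the unmutated set stays open: 24.8% of the genes lower in the mutated set lie there against 3.9% of placed tested genes (odds ratio 9.67). A shared change in regulation of that chromosome was not tested, and no DNA was analysed. With the chromosome 15 median in the model, 6 of 609 genes on other chromosomes were called again, but the median absolute change of the 609 moved only from 0.547 to 0.5 while the median SE of all called genes rose from 0.132 to 0.164. The absolute change disregards sign, so it does not show whether the 609 genes kept their direction. Mutation status and chromosome 15 dose cannot be told apart for these genes, because the high medians fell in 7 of 10 and 1 of 11 lymphomas. The Ikzf1 mutation itself, which the design names, could account for them and was not tested apart from it.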

How the results depend on the processing

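Leaving out single lymphomas, the covariates, the rank-sum test, the depth limit and omission of chromosome 15 were chosen after the data were seen; the other settings were not. No paired analysis was possible because nothing in the labels ties a thymus sample to the animal of a lymphoma. For lymphomas against thymus the count stayed within 3215 to 4785 under 7 settings (RLE factors 4057, no filter 4009, CPM minimum 3946, DESeq2 4785, TPM 4024 and 4090, depth limit 3215 with 9 lymphomas), but was 8777 with limma-voom, 1907 with a log2 fold change of at least 1 and 1929 to 4435 when 1 library was left out. On log2(TPM + 0.1) the median of all genes was -0.10, against 0.07. For the mutated set against thymus the count was 7866 with limma-voom, 1651 with the fold limit and 1441 to 2128 without 1 thymus library. For the unmutated set it was 8308, 2298 and 2856 to 3284. Between the sets it was 1269 with DESeq2, 207 with the fold limit, 388 in lymphomas alone, 225 with the rank-sum test, 9 with the chromosome 15 median in the model and 301 to 1221 when 1 lymphoma was left out, against 704 with RLE factors, 709 with limma-voom (486 genes shared), 798 with library size (623 shared) and 548 without chromosome 15 (544 shared). The fold limit lowers counts by construction; for the other settings the cause was not tested. With an estimated correlation 0 lists passed in each comparison, against 13, 12, 13 and 14; fry passed 13, 10, 18 and 4. Without 1 thymus library 12 to 14, 11 to 12 and 13 to 15 lists passed against thymus. The region within 10 Mb of Ikzf1 had medians of -0.03, -0.12 and -0.08. Directions turned for the following genes, and the cause was not tested. Fignl1 against thymus was -0.17 with limma-voom, -0.14 on each TPM scale, -0.24 in deep libraries and -0.13 to 0.18 when 1 library was left out. In the mutated set against thymus, Grb10 was -0.16 with limma-voom and Ikzf1 -0.14 to 0.03 when 1 thymus library was left out. Between the sets, Ikzf1 was -0.05 with limma-voom, and Prlr 0.25 with DESeq2, 2.29 with the chromosome 15 median and -5.51 to 0.96 when 1 lymphoma was left out. With the chromosome 15 median Ddc was 0.02, Bcl11b -0.08, Notch1 -1.17 and Myc -0.20, and without 1 lymphoma Bcl11b was -0.02 to 0.21 and Myc -0.03 to 0.20. Ikzf1 passed with limma-voom for all lymphomas (-0.78) and the mutated set (-0.86), and for the unmutated set in a fit of 2 groups on the authors' filtered table (-0.71). Fignl1 passed with limma-voom for the mutated set (-0.43). The adjusted p of Ikzf1 ranged over the alternatives from 0.0224 to 0.705, 0.0436 to 1 and 0.0232 to 0.342 in these 3 comparisons, and that of Fignl1 in the mutated set from 0.039 to 0.766. The same 6 lymphomas were low over chromosome 11 and 8 were high over chromosome 15 with CPM minima of 1 and 50. The Grb10 comparison with its alternatives and receptor segment shares were not run. Depth limits genes near the floor, such as Zcchc12.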

Other observations

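The values in this part were chosen after the data were seen, apart from the lists, which were not.

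Several other lists were measured in lymphomas against thymus without passing as lists. Of 15 Notch targets 3 rose and 1 fell, with Heyl (log2 fold change 6.49) and Myc higher and Ccnd3 (-2.09) lower. Of 24 p53 targets 5 rose, such as Ei24 (1.00), and 4 fell, such as the death receptor gene Fas (-2.81) and Btg2 (-1.72). Of 15 early thymocyte genes Hes1 rose (3.05) and Tcf7 fell (-0.53). The oncogene list held 2 rises and 7 falls among 19 genes, with Mycn at -5.42, and the tumour suppressor list 3 and 4 among 22, with Fbxw7 at -0.79. Among 19 apoptosis genes Bcl2l1 (-2.58), Mcl1 (-0.78) and 1 other fell and Bak1 (0.60) rose. Of 20 NF-kB genes 2 rose and 4 fell (Traf1 -3.08, Nfkbiz -1.43, Nfkbia -1.42), and of 15 immediate-early and heat shock genes 2 rose (Hspa8 1.03) and 5 fell (Jund -1.65, Dnajb1 -0.64). Mitosis genes had 1 rise among 25 (Bub1b 0.88), cholesterol synthesis 3 rises and 1 fall among 21 (Stard4 0.83, Pmvk -0.63), and PI3K genes 3 and 4 among 29 (Insr -0.75, Pik3ca -0.60, Akt2 -0.40).

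Imprinted genes held 3 rises and 2 falls among 14 (Cd81 0.85, Peg10 -4.58, Sgce -3.80), neighbours of Ikzf1 2 rises among 13 (Plek 1.57, Ddc), the Ikaros family 1 fall among 5 (Ikzf4 -2), and histones none among 15. For other cell types, B-cell markers had 0 changes among 10, plasma cells 1 rise (Sdc1 5.00) and 1 fall (Xbp1 -1.42) among 5, dendritic cells 1 fall among 13 (Siglech -2.64), gamma-delta T cells 1 rise among 4 (Sox13 2.11), endothelium 1 rise among 4 (Egfl7 1.55) and erythroid cells 2 rises and 1 fall among 8 (Klf1 2.73, Car2 -5.26). Adjusted camera p for these lists ran from 0.066 for NF-kB to 0.968 for endothelium. The test pointed down while the mean was above 0 for PI3K genes (median -0.02, mean 0.45), tumour suppressors (0.10 and 0.23), imprinted genes (0.46 and 0.95), B cells (0.18 and 0.04) and plasma cells (-0.52 and 0.42). Among lists that did not pass between the Ikzf1 sets, the test there pointed up for p53 targets (median 0.01, mean -0.04), imprinted genes (-0.08 and 0.45), plasma cells (-0.14 and -0.09) and endothelium (-0.03 and 0.26) and down for epithelium (0.02 and -0.02). Single genes of lists that did not pass there were Pmaip1 (2.25), Tnfaip3 (0.79), Pfkp (0.76), Runx1 (0.62) and Dnmt3a (0.30), all higher in the mutated set, and Bst2 (-1.2), lower.

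Single lymphomas stood out. Notch1 was below the thymus range in lymphomas 7 (76.5 CPM), 12 (52.7), 18 (52.3) and 35 (180). Chromosome 14 had a median log2 ratio of 0.56 in lymphoma 12, 0.33 in 20, 0.59 in 30 and 0.34 in 32, chromosome 16 of 0.35 in 34, chromosome 18 of 0.43 in 35, chromosome 19 of 0.44 in 7 and chromosome 2 of 0.34 in 16, and no chromosome had a median at or below -0.3.

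Among 3234 pairs of a lymphoma and a 5 Mb window (154 windows), 56 had a median of -0.5 or lower, 15 of them on chromosome 11, while no thymus library went below -0.21. Lymphoma 2 was low over chromosome 2 from 150 to 170 Mb (-0.88, -0.75, -0.70 and -0.74 in successive windows), lymphoma 16 over chromosome 5 from 20 to 25 Mb (-0.84) and 30 to 35 Mb (-0.91), and lymphoma 22 over chromosome 16 from 0 to 5 Mb (-1.05) and 10 to 20 Mb (-0.86 and -0.69). Chromosome 4 from 145 to 150 Mb was at -1.82 in lymphoma 15 and -2.34 in 18. Chromosome 12 from 100 to 105 Mb was low in lymphomas 7, 9, 12, 14 and 15 (-0.71 to -1.1), and from 110 to 115 Mb in lymphomas 9, 15, 17, 20, 22 and 30 (-0.59 to -0.87). The window low in the largest number of lymphomas was chromosome 6 from 45 to 50 Mb (26 genes), low in lymphomas 4, 12, 19, 21, 22, 30, 31, 32 and 34 (-0.52 to -1.2).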
